A study of Mus musculus and Homo sapiens with 11 samples.

How the data were processed

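The data were 11 single-channel expression arrays of biotin-labelled cRNA, 6 from C2C12 mouse myoblasts and 5 from H1299 human lung carcinoma cells. Per the labels, the C2C12 cells carried either a mock vector or the DeltaNp73 construct, a form of p73 without the amino-terminal activation domain, and were taken at 0, 6 and 24 h after the onset of differentiation. The construct library of 24 h is labelled DeltaNp72, which is no known gene name, and it was used as the construct library of its time. The H1299 cells were infected with adenovirus that delivered GFP, p53, a truncated p53, p73 or a truncated p73. Every condition had 1 library, so no condition had replicates.

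Per the labels and the deposited values, the unit was intensity on a linear scale, with 45101 probe sets on the mouse array and 22277 on the human array. From the values, each deposited column had been scaled by the authors so that its mean without the lowest and the highest 2% was about 500. The algorithm that made the intensities and its version were not given in the sources used here, and neither were detection calls. Array data carry no counts, so the number of libraries limits the precision.

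Control probe sets were left out (64 mouse, 62 human). Probe sets that the platform table paired with exactly 1 gene symbol were kept, 34945 for 18193 mouse genes and 19064 for 11963 human genes, which left out 932 and 1043 with several symbols and 9160 and 2108 with none. Intensities were floored at the 50th percentile of all values of a platform, 76.1 for the mouse and 107.4 for the human array, and then put on the log2 scale. The probe set with the highest mean stood for its gene. A gene was measured in a pair of libraries when at least 1 of them lay above the floor, and in a fit when at least 2 did. A difference with 1 side at the floor is given as a lower bound, and fitted sizes of genes with libraries at the floor are distances from the floor. Values of the p53 gene itself are not analysed here.

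Additive models were fitted across all genes with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. In C2C12 the model held the construct and the time, which left 2 residual degrees of freedom. In H1299 the 4 constructs together were set against GFP with 3 residual degrees of freedom, and a layout of family member by truncation over the 4 construct libraries left 1. The spread in these fits is the departure from additive effects, not the spread of replicates, and a lone library is assumed to vary like the others. Single pairs of libraries were compared without a test, as log2 differences and as counts of genes at least 2-fold apart. Libraries that differ by the residual spread of the additive fits alone would have 24.65 mouse genes and 124.9 human genes at least 2-fold apart, as the mean of 20 simulated draws. That spread also holds real departures from additive effects, so these are no estimates of technical noise.

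Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the settings listed here except where said. The mouse lists covered the sarcomere, muscle membrane and metabolism, myogenic regulators, inhibitors of myogenesis, cell cycle exit, p53 target genes, mitosis, DNA replication, immediate early genes, IGF signalling, extracellular matrix, the interferon response, NF-kB and inflammation, endoplasmic reticulum and amino acid stress, cholesterol synthesis, ribosomal proteins, and markers of adipocytes, osteoblasts, smooth muscle and fibroblasts, and blood cells. The human lists covered p53 targets of arrest and repair, p53 targets of apoptosis, genes linked to p63 and p73, mitosis, DNA replication, the interferon response, NF-kB and inflammation, endoplasmic reticulum and amino acid stress, cholesterol synthesis, immediate early genes, matrix and mesenchymal genes, histones, ribosomal proteins, and markers of epithelial and blood cells. In the fits, lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of an organism. In single pairs a list's median was placed among 10000 random lists of equal size matched on expression in 20 bins.

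Named genes were the 12 largest and the 12 smallest differences that passed the threshold in a fit, of the same sign at all times for the construct effect, or the 6 largest of each sign where none passed. In pairs they were the 12 largest of each sign with a library above 4 times the floor. Up to 4 members of each list with the largest absolute difference were added, together with the p53 family genes and CDKN1A, MDM2, Cdkn1a, Mdm2, Myog, Myod1, Cdkn1c and Rb1. Fits that pooled 0 h and 6 h as an early stage in each C2C12 arm were added after the data were seen. Their residual spread is the change from 0 h to 6 h within each arm, part of which is real, and not replicate spread.

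Alternatives were quantile normalization, scaling to a common median, floors at the 30th and 70th percentiles, no floor and no filter, the mean of a gene's probe sets, every probe set on its own, eBayes without trend and robust, leaving out each library, no time factor, leaving out both 24 h libraries, and the GFP library as an added level. The fits were checked on simulated data with 200 changed genes per effect: among 67 genes changed by 1 on the log2 scale they recovered 67 for the construct effect, 66 for each time effect, 65 for the 4 constructs against GFP, 59 for p73 against p53 and 63 for truncated against full. Between 6 and 19 unchanged genes were called in each. The changed genes were drawn from those well above the floor, the spread came from the variance trend of each fit, and the effects were additive. These shares therefore do not tell how many changes the fits miss among low genes or where effects are not additive. Of 40 unshifted lists, 1 lay outside the middle 95% of random lists. Those lists were drawn at random from genes simulated as independent. The check therefore does not cover lists whose genes vary together, for which matched random lists may be too narrow. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.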

Results

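The C2C12 libraries ask how DeltaNp73 bears on differentiation. In mock C2C12 cells the muscle programme appeared within 24 h of the onset of differentiation. Myog, the transcription factor of terminal myogenesis, had an intensity of 53.9 at 0 h, 245 at 6 h and 3193 at 24 h. Myl1 and Mylpf, myosin light chains of fast fibres, were at least 125-fold and at least 90.2-fold higher at 24 h than at 0 h, and the troponins Tnnc2 and Tnni1 at least 37.1-fold and at least 32.6-fold higher. Acta1, skeletal actin, was 28.3-fold higher and Actc1, cardiac actin, was 25.2-fold higher. Genes of cell division were lower, among them the mitotic kinase Nek2 by -2.67 on the log2 scale and Trip13, a chromosome checkpoint gene, by -2.60.

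At 6 h, 108 genes were at least 2-fold higher and 92 at least 2-fold lower than at 0 h in the mock cells, or 127 and 67 after quantile normalization and 90 and 112 after scaling to a common median. At 24 h the counts were 777 and 709, or 739 and 750 after quantile normalization. The early change was led by cholesterol synthesis, whose list median was 1.98 on the log2 scale at 6 h and 2.98 at 24 h. Hmgcs1 and Idi1, enzymes of the mevalonate pathway, were 8.68-fold and 6.35-fold higher at 6 h. Id1, Id2 and Id3, which block myogenic transcription factors, were lower by -2.56, -2.15 and -3.19 at 6 h. The median of the inhibitors of myogenesis was -0.34 at 6 h, while Bhlhe40 of the same list was 4.51-fold higher at 24 h. At 24 h the list medians were 1.92 for the sarcomere, 0.96 for muscle membrane and metabolism, 0.80 for myogenic regulators and 0.80 for the interferon response. Those of mitosis and DNA replication were -1.71 and -1.63. Each of these 24 h medians lay at the edge of its matched random lists, at a percentile of at least 99.95 or at 0.

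With 0 h and 6 h pooled as an early stage, so that the residual spread is the 0 h to 6 h change within each arm and the 24 h stage is 1 library, 299 genes rose and 510 fell in the mock cells at 24 h (limma, adjusted p under 0.05), or 415 and 374 after scaling to a common median. Myl1 rose by 6.22 on the log2 scale (adjusted p = 0.0212), Acta1 by 4.95 (adjusted p = 0.0139), Saa3, an acute-phase protein, by 4.60 and Myog by 4.55. Myl4, Actc1, Myom2, Tnnt1, Tnni2 and Tnnc1, all of the contractile apparatus, rose by between 3.86 and 4.52, as did Aldoc, an aldolase, by 4.09. Of 21 measured sarcomere genes 11 rose (15 adjusted over the list alone). Of 30 mitosis genes 29 fell, such as Nek2, Foxm1, Plk1 and Aurkb, which are kinases and a transcription factor of the division programme (30 adjusted over the list alone). Of 27 DNA replication genes 20 fell, among them Cdc6, which loads the replicative helicase, by -2.15 (25 adjusted over the list alone). Igf2, a growth factor of myoblasts, rose by 3.31, Atp2a1, the calcium pump of fast muscle, by 3.31, Dcn and Postn of the matrix by 3.74 and 3.33, and Ifit3 of the interferon response by 2.88. Among the genes that fell most were Cmss1 by -3.02, the kinetochore gene Ska3 by -2.59, Acsbg1 by -2.56, Etv4 by -2.44, Snhg3 by -2.43, Bora by -2.43, Depdc1b by -2.42 and Espl1, the separase gene, by -2.31. camera called the sarcomere (adjusted p = 1.42e-10) and mitosis (adjusted p = 2.22e-18) lists, with adjusted p = 0.361 and adjusted p = 0.637 with an estimated correlation. It also called DNA replication (adjusted p = 1.39e-14), muscle membrane and metabolism, extracellular matrix, the interferon response, IGF signalling, myogenic regulators and cholesterol synthesis, with adjusted p between 0.417 and 0.838 with an estimated correlation. Leaving out any of the 4 early libraries in turn, or eBayes without trend and robust, left 0 genes, and the mean of probe sets left 15 (limma, with 3249 genes at an unadjusted p under 0.05 in the pooled fit).

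In the cells with the construct the muscle and mitosis genes showed no such change at 24 h. Myog had intensities of 33.2, 28.8 and 37.0 at 0, 6 and 24 h, all below the floor, and Acta1 had 314, 262 and 283. Nek2 had 2617, 2745 and 2794. The sarcomere median of 24 h against 0 h was -0.08, that of mitosis -0.03 and that of the interferon response -0.07. DNA replication was lower, with a median of -0.34 and 25 of 27 genes negative (percentile 0). In the fit that pools 0 h and 6 h, 0 genes passed in these cells (limma, 193 at an unadjusted p under 0.05). There camera called DNA replication down (median -0.17, adjusted p = 0.00626), immediate early genes down (-0.37), and stress genes (0.26) and muscle membrane and metabolism (0.10) up, all with adjusted p = 0.965 with an estimated correlation. The early response was present, with a cholesterol synthesis median of 1.68 at 6 h and 1.64 at 24 h, and Id1, Id3 and Id2 lower by -2.56, -2.42 and -1.74 at 24 h. The list of endoplasmic reticulum and amino acid stress had medians of 0.44 at 6 h and 0.64 at 24 h. Its member Cth, which makes cysteine, was 8.76-fold higher at 24 h, and Trib3, a pseudokinase of the stress response, was 7.13-fold higher. Lower at 24 h were Il6, an inflammatory cytokine, by -2.76, Ereg, an EGF family ligand, by -1.87, and Egr1, an immediate early transcription factor, by -1.69. In all, 114 genes were at least 2-fold higher and 161 lower at 6 h (132 and 124 after scaling to a common median, 297 and 298 over every probe set), and 148 higher and 130 lower at 24 h (185 and 92 after that scaling).

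**Figure D1:**
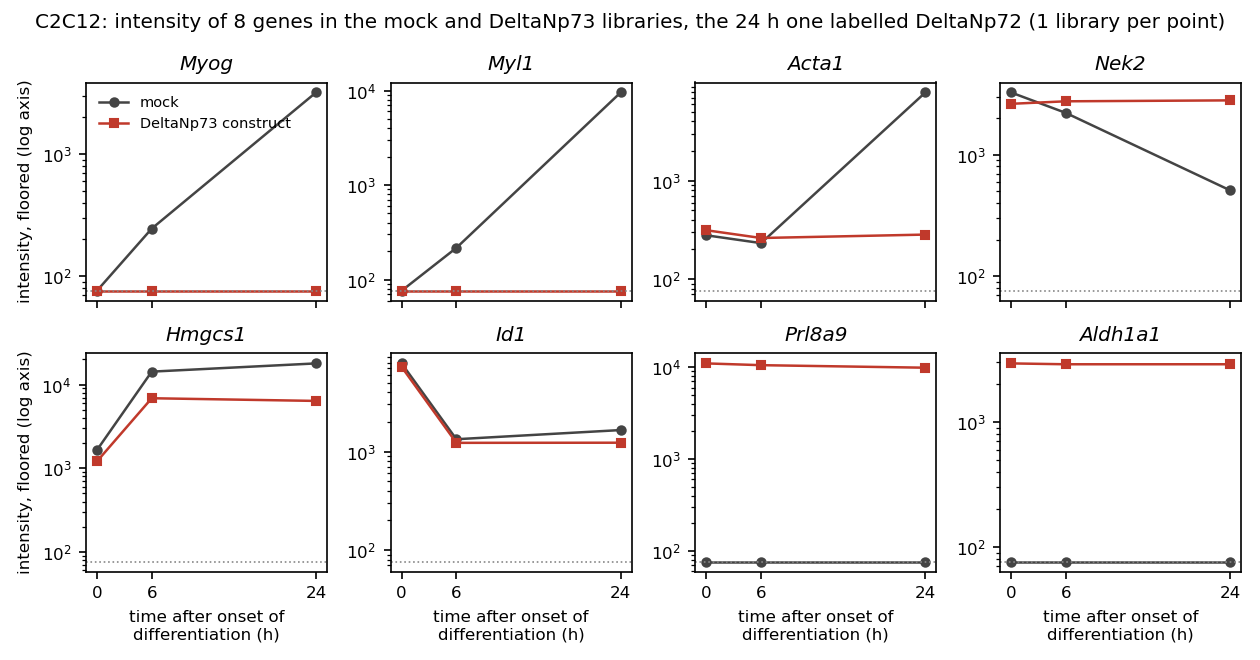
Floored intensity on a log axis against hours after the onset of differentiation for 8 C2C12 genes, with 1 library per point, mock in grey and the DeltaNp73 construct in red, its 24 h library being labelled DeltaNp72. Myog reaches 3193 in the mock library of 24 h and stays at the floor of 76.1 (dotted) with the construct, while Id1 is lower after 0 h in both arms and Prl8a9 is above the floor in the construct libraries alone.

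Across genes, the 24 h changes of the mock and of the construct cells had a Pearson r of 0.21 and a Spearman rho of 0.18 over 12117 genes, which are not independent replicates. For 6 h against 0 h the values were 0.45 and 0.39. Genes at least 2-fold higher at 24 h in both arms numbered 56, against 9.49 for independent lists, and 16 went opposite ways. The changes at 6 h and at 24 h of the construct cells share their 0 h library and had an r of 0.78, where a shared library alone gives 0.50. Their covariance was 0.116 against 0.0434 from the residual spread, with 90 genes higher at both times against 1.46 for independent lists and 1.1 with a shared library at the residual spread. In the mock cells the r of 6 h and 24 h was 0.56, with a covariance of 0.144 against the same 0.0434 and 85 genes higher at both times against 7.16 for independent lists.

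Some genes that stayed at the floor in mock cells were high in the construct libraries from 0 h on. The labels do not tell whether the times of an arm are separate cultures, so equal differences at every time are not replicates. An effect of the construct is thus not separated from a lasting difference between the arms. Prl8a9, a prolactin family hormone, was at the floor in the mock libraries and at least 145-fold, 138-fold and 130-fold higher with the construct at 0, 6 and 24 h. Aldh1a1, which makes retinoic acid, was at least 38.7-fold, 38.1-fold and 38.1-fold higher. Sprr1b, Sprr2k and Sbsn, genes of the cornified envelope of skin, rose by 3.98, 3.56 and 2.85 on the log2 scale. Car3, a carbonic anhydrase, fell by 3.25, and Pdk4, which restrains pyruvate oxidation, fell by 1.79.

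In the additive fit over the 6 libraries 50 genes rose and 23 fell with the construct (limma, 11274 genes, adjusted p under 0.05), each with the same sign at all 3 times. Prl8a9 (adjusted p = 0.000158) and Aldh1a1 (adjusted p = 0.000745) rose from the floor. So did Sprr1b, Vnn1, Gsta3, Hsd17b2 and Perp, while St8sia4, Rhox5 and Igfbp3 fell to it in all construct libraries, and Sprr2k, Gda, Klhl13, Tnfrsf9 and Itgb3 were at the floor in some libraries. Fitted sizes of these genes are distances from the floor, which understate the change. Vnn1, a pantetheinase, rose by 3.78, Gda, a guanine deaminase, by 3.67, and Gsta3, a glutathione transferase, by 3.32. Tpsab1, a mast cell tryptase, Cck, a peptide hormone, Serpinb9b, a protease inhibitor, and Hsd17b2, a steroid dehydrogenase, rose by 3.05, 2.97, 2.95 and 2.81. Genes that fell included Klhl13 by -3.04, Nptx1, a neuronal pentraxin, by -2.81, St8sia4, a polysialyltransferase, by -2.63, Tnfrsf9 by -2.53, Plac8 by -2.32, Flrt2 by -2.12, Rhox5 by -2.06, the lectin gene Lgals2 by -1.90 and the integrin subunit Itgb3 by -1.91, of which another probe set went the opposite way at 6 h. From the lists, Perp, a p53 target of desmosomes, rose by 2.32, Ptgs2, the inducible cyclooxygenase, rose by 1.72, and Igfbp3, Irs1 and Ccng1 fell by 1.61, 1.33 and 0.85. The count became 1480 without the mock library of 24 h, 1471 without the construct library of 24 h and 1495 without both, and between 20 and 35 without any other library. It was 110 after scaling to a common median, 114 with a floor at the 30th percentile, 17 at the 70th, 39 with the mean of probe sets and 135 with no time factor.

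Of 13 cholesterol synthesis genes all were negative with a median of -0.999, 0 fell over all genes (limma) and 6 did adjusted over the list alone, with Lss at -1.67 and Idi1 at -1.52. camera called this list (adjusted p = 1.3e-06), with adjusted p = 0.714 with an estimated correlation, which was also the value of each further list called here. At the preset correlation it called mitosis with a median of 0.54 and 30 of 30 positive, DNA replication with 0.46 and 27 of 27 positive, the sarcomere with -1.20 and muscle membrane and metabolism with -0.24. These values rest mainly on 24 h. At 0 h, 6 h and 24 h the pair medians were -0.22, 0.26 and 1.53 for mitosis, with 23 of 30 genes negative at 0 h, 0.06, 0.06 and 1.23 for DNA replication, and 0.04, -0.03 and -2.69 for the sarcomere. For muscle membrane and metabolism they were 0.01, -0.19 and -1.12, and for the interferon response 0.08, -0.19 and -0.96. It also called endoplasmic reticulum and amino acid stress (0.31), IGF signalling (-0.53, with 2 of 12 fallen and 5 adjusted over the list alone), the interferon response (-0.33), extracellular matrix (-0.20) and p53 target genes (-0.17, with 1 of 28 risen and 1 fallen). The lists not called had medians of -0.41 for myogenic regulators, -0.18 for cell cycle exit, 0.00 for immediate early genes, -0.07 for inhibitors of myogenesis, 0.16 for NF-kB and inflammation and 0.03 for ribosomal proteins. Markers of other cell types were not called either, with 0.01 for adipocytes, -0.04 for osteoblasts, 0.17 for smooth muscle and fibroblasts and -0.13 for blood cells.

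By time, the construct libraries had 248 genes at least 2-fold higher and 177 lower than mock at 0 h (226 and 217 after scaling to a common median, 442 and 453 over every probe set), 208 and 172 at 6 h (365 and 397 over every probe set), and 720 and 864 at 24 h (822 and 785 after quantile normalization). Across genes, the differences at 0 h and 6 h had a Pearson r of 0.62 and a Spearman rho of 0.46, with 73 genes lower at both times against 2.59 for independent lists. For 0 h and 24 h the r was 0.29 and for 6 h and 24 h 0.49. At 0 h Fst, the activin antagonist follistatin, and Saa3 were 12.1-fold and 10.9-fold higher, and NF-kB and inflammation had a median of 0.42 (percentile 100). At 6 h Vldlr, a lipoprotein receptor, was at least 14.2-fold higher and Pdlim3, a Z-disc gene, at least 17.8-fold lower. At 24 h Myl1, Myog and Ttn, the titin gene, were at least 125-fold, 42.0-fold and 33.8-fold lower, respectively. Cdkn1a, the inhibitor of cyclin-dependent kinases, had 2675, 3670 and 6369 in mock and 3145, 2873 and 2613 with the construct. Myod1 had 1798, 786 and 1720 in mock and 1448, 705 and 691 with the construct, and Rb1 had 1933 and 1238 at 24 h. Mdm2 had between 1396 and 1458 with the construct and between 1882 and 2324 in mock. Trp73 and Trp63 stayed below the floor in every library, so the signal of Trp73, at 63.7, 60.7 and 45.7 in the construct libraries and 41.9, 38.9 and 36.3 in mock, does not verify the construct, and so did Cdkn1c except for 82.7 in the mock library of 6 h.

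The difference of the 24 h changes, construct minus mock with the early stage pooled, called 0 genes (limma, smallest adjusted p = 0.0798, 1983 at an unadjusted p under 0.05). Acta1 had -4.97, Mylpf -6.06, Myog -4.55 and Nek2 2.45 in this contrast. In the additive fit, 0 genes passed for 6 h against 0 h (limma, 685 at an unadjusted p under 0.05) and 0 for 24 h against 0 h (1394), where Id1 had -2.56 and -2.40 and Insig1, a sensor of sterols, 2.80 and 3.34. Without the construct library of 24 h these counts became 886 and 3873, and without the mock library of 24 h 903 and 421. The cholesterol synthesis list had 13 of 13 members risen at 6 h adjusted over the list alone, with adjusted p = 0.594 with an estimated correlation.

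In H1299 cells, which lack p53, the libraries labelled p73 and truncated p73 carried the strongest response of p53 target genes. GDF15, a stress cytokine, was at least 32.3-fold and at least 95.8-fold higher in them than in GFP cells. MDM2, the ubiquitin ligase of p53, was higher by 3.84 and 4.25 on the log2 scale, and CDKN1A was 8.94-fold and 14.5-fold higher. In the library labelled p53, CDKN1A was 4.42-fold higher, DRAM1, a lysosomal gene of autophagy, 8.14-fold higher, and S100A2, a calcium-binding protein of epithelia, 11.5-fold higher. TP73 itself had intensities of 25983 and 19698 in the libraries labelled p53 and truncated p53, and 2.73, 2.57 and 10.6 in those labelled GFP, p73 and truncated p73, which goes against the labels. The libraries are therefore named by their labels throughout.

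**Figure D2:**
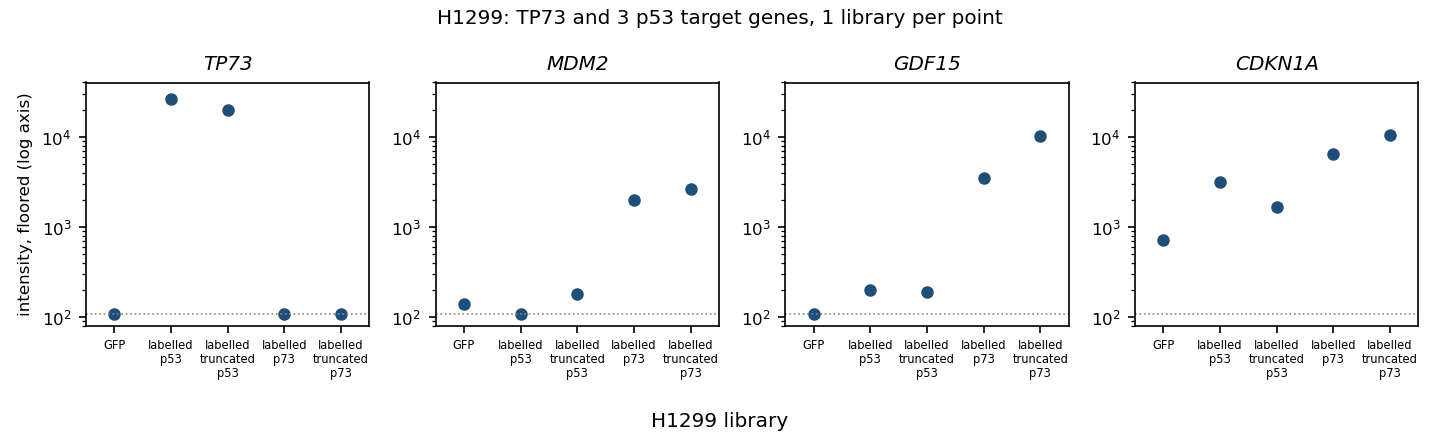
Floored intensity on a log axis of TP73, MDM2, GDF15 and CDKN1A in the 5 H1299 libraries, 1 library per point, with the floor of 107.4 dotted. TP73 is at 25983 and 19698 in the libraries labelled p53 and truncated p53 and at the floor in the others, while MDM2 is at 1999 and 2651 in those labelled p73 and truncated p73.

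Against GFP, the library labelled p53 had 223 genes at least 2-fold higher and 101 lower (343 and 337 over every probe set), and that labelled truncated p53 had 44 and 14. The library labelled p73 had 76 and 68 (91 and 46 after scaling to a common median), and that labelled truncated p73 had 191 and 147 (246 and 113). The residual spread of the fit over the 4 construct libraries corresponds to 124.9 such genes, and since it also holds real departures from additive effects it is no estimate of noise alone. In the library labelled p53, SFN, a 14-3-3 protein of epithelia, was at least 5.98-fold higher, JAG2, a Notch ligand, 4.35-fold, VDR, the vitamin D receptor, 4.21-fold, and the metallothionein MT1H 6.40-fold. CDC6, CCNE2, a cyclin of S phase entry, and MCM10, a replication factor, were lower by -1.97, -1.75 and -1.70. In the library labelled truncated p53, S100A2, MT1H, DRAM1 and JUNB were higher by 1.97, 1.94, 1.68 and 1.58, and E2F8 and CCNE2 lower by -1.48 and -1.44. In the library labelled p73, PLK3, a stress kinase, was at least 9.10-fold higher, RRAD, a small GTPase, 6.77-fold, TP53I3, an oxidoreductase of the apoptotic response, 5.92-fold, DDB2, of nucleotide excision repair, 5.04-fold, and APAF1, of the apoptosome, 4.44-fold. CDC25A, a phosphatase of the cell cycle, was at least 5.48-fold lower, and MYBL2 and AURKB were lower by -1.56 and -1.52. In the library labelled truncated p73, PLK3 was at least 15.3-fold, RRAD 12.7-fold, CYFIP2 11.8-fold and ACTA2, smooth muscle actin, 8.67-fold higher, and CDC45, FEN1 and CDC25C, genes of replication and mitotic entry, were lower by -2.35, -2.10 and -2.02.

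List medians against GFP are given in the order of the labels p53, truncated p53, p73 and truncated p73. The p53 targets of arrest and repair had 0.48, 0.36, 1.53 and 1.59, and those of apoptosis 0.67, 0.46, 0.80 and 1.21. Genes linked to p63 and p73, such as JAG2, SFN and VDR, had 1.67, 0.73, 0.42 and 0.78. Mitosis had -0.47, -0.23, -0.67 and -1.17, and DNA replication -0.95, -0.56, -0.80 and -1.22. The 20 medians of these 5 lists lay at percentiles of at least 99.95 or at 0 of their matched random lists. NF-kB and inflammation had 0.19, 0.14, 0.05 and 0.62, with NFKBIA, the NF-kB inhibitor, at 2.10 in the library labelled truncated p73. Ribosomal proteins had 0.13, 0.11, 0.41 and 0.52, of which the latter 2 became -0.005 and 0.03 after quantile normalization. In the same libraries the 3' to 5' signal of actin, a sign of RNA quality, was 2.16, 1.22, 1.74 and 1.61, against 1.32 in GFP. That of GAPDH varied less, with 0.99, 0.93, 0.92 and 0.96, against 0.91 in GFP.

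**Figure D3:**
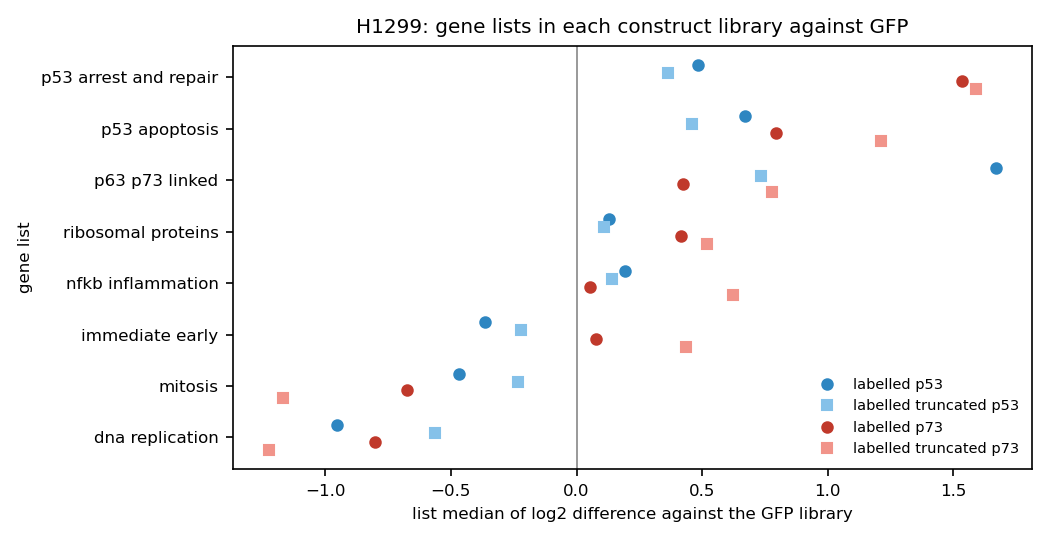
Median log2 difference from the GFP library (horizontal axis) of 8 gene lists (vertical axis) in the 4 H1299 construct libraries, with circles for full and squares for truncated forms and colours for the labelled family member. The arrest and repair list lies at 1.53 and 1.59 in the libraries labelled p73 and truncated p73 and at 0.48 and 0.36 in those labelled p53 and truncated p53, and the ribosomal values of the first 2 are near 0 after quantile normalization.

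Tested together against GFP, the 4 constructs called 0 genes (limma, 6908 genes, smallest adjusted p = 0.649, 279 at an unadjusted p under 0.05). DRAM1 had 2.23, GDF15 3.32, CDKN1A 2.60, CCNE2 -1.68, E2F8 -1.57 and CDC25A -1.78 in this fit. All 19 genes of arrest and repair were positive with a median of 1.08, and 2 rose adjusted over the list alone. Of 27 DNA replication genes 26 were negative with a median of -0.88, and 15 fell adjusted over the list alone. camera called both lists, p53 apoptosis (0.65), genes linked to p63 and p73 (0.87), mitosis (-0.60), cholesterol synthesis (-0.30) and ribosomal proteins (0.29, and 0.01 after quantile normalization). With an estimated correlation the smallest was adjusted p = 0.285. The lists not called had medians of 0.24 for the interferon response, 0.35 for NF-kB and inflammation, -0.08 for endoplasmic reticulum and amino acid stress, 0.01 for immediate early genes, -0.07 for matrix and mesenchymal genes, 0.06 for histones and -0.12 for epithelial markers, and the only measured blood cell marker, ITGAM, had 0.61.

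Across genes, the differences from GFP of the libraries labelled p53 and truncated p53 had an r of 0.66, where a shared GFP library alone gives 0.50, and a covariance of 0.101 against 0.0804 from the residual spread. For p73 and truncated p73 the r was 0.63 and the covariance 0.124, with 60 genes higher in both against 2.04 for independent lists and 8.6 with a shared library at the residual spread. Between the family members the r was 0.37 for the full and 0.50 for the truncated forms, with covariances of 0.0688 and 0.0786. Since the residual spread holds differences between constructs, these values do not tell how much is shared beyond the GFP library. For p53 and truncated p53, 35 genes were higher in both against 1.41 for independent lists and the same 8.6 with a shared library.

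The contrast of the family members across both forms called several p53 target genes. Their lists were not called with an estimated correlation, a test with 1 degree of freedom here that could hardly call any list. GDF15, MDM2 and PLK3 rose by 4.95, 4.05 and 3.15 on the log2 scale in the libraries labelled p73 relative to those labelled p53. CDKN1A rose by 1.82, APAF1 by 1.87, TP53I3 by 1.73 and PMAIP1, a BH3-only protein that triggers apoptosis, by 1.65. TP73 lay below the floor in both and was at least 242-fold and at least 183-fold lower than in those labelled p53 and truncated p53. VDR fell by 1.94, S100A2 by 1.45 and the heat shock cofactor DNAJB1 by 1.42. FOXM1, which drives mitotic transcription, fell by 1.27.

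In this fit 92 genes rose and 39 fell (limma, 6853 genes), or 159 and 34 after scaling to a common median. The adjusted p was 5.78e-11 for GDF15, 2.14e-18 for MDM2, 0.0395 for CDKN1A and 8.18e-43 for TP73, whose fitted size depends on the floor, with differences of the same sign in both forms. CYFIP2, of actin regulation, RRAD, ENC1, ID3 and ATF3, a stress transcription factor, rose by 2.11, 1.98, 1.96, 1.91 and 1.85, and the histone gene H2AC17 by 2.02. Genes that fell included ROGDI by -1.66, the homeobox gene DLX2 by -1.51, UPP1, of uridine breakdown, by -1.49, NTSR1 by -1.41, CBR3 by -1.36, KREMEN2 by -1.34 and ZMIZ1 by -1.32, and CDC25A, at the floor in both libraries labelled p73. Of 19 genes of arrest and repair 11 rose (16 adjusted over the list alone), with adjusted p = 0.638 with an estimated correlation. Before adjustment camera's p for this list went from 1.7e-42 at the preset correlation to 0.0425. The estimated correlation was -0.029, below the preset one, so a higher correlation does not account for that move. Of 14 genes of apoptosis 5 rose (8 adjusted over the list alone), with adjusted p = 0.736 with an estimated correlation. That value also held for mitosis, where FOXM1 and 1 other of 31 fell (10 adjusted over the list alone), for immediate early genes, where 2 of 16 rose and 1 fell, and for ribosomal proteins, where 7 of 15 rose (14 adjusted over the list alone) with a median of 0.35 that became 0.01 after quantile normalization. The other lists were not called by camera, with medians of -0.17 for DNA replication, where PCNA rose and FEN1 fell, -0.08 for genes linked to p63 and p73, 0.30 for NF-kB and inflammation, 0.18 for the interferon response, 0.01 for cholesterol synthesis, 0.03 for endoplasmic reticulum and amino acid stress, 0.05 for matrix and mesenchymal genes, -0.05 for histones and 0.30 for epithelial markers. With 1 residual degree of freedom the calls rest on the pooled variance: 4 genes passed without trend and robust, 1 with the mean of probe sets, 52 with every probe set on its own and 23 with a floor at the 30th percentile or none.

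As single pairs, the full forms differed by 108 genes at least 2-fold higher with the p73 label and 273 lower (132 and 205 after scaling to a common median, 363 and 422 over every probe set), and the truncated forms by 122 and 69 (153 and 54). Arrest and repair had medians of 1.01 and 1.11 and mitosis -0.15 and -0.92. Across genes the r of these independent pairs was 0.18 and the rho 0.06. Higher in both were 26 genes, against 1.83 for independent lists.

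The truncated forms differed from the full forms in opposite directions in the 2 family members for several gene lists. In the libraries labelled p53, the truncated form was lower than the full form for DRAM1 by -1.34, S100A2 by -1.55, JAG2 by -1.22 and CDKN1A by -0.92, and the median of genes linked to p63 and p73 was -1.02. In those labelled p73, the truncated form was higher for LAMA5, a laminin chain, by 2.11, NOTCH1, a receptor of cell fate, by 1.84, BCL2L1, an apoptosis inhibitor, by 1.63, GDF15 by 1.57 and ATF3 by 1.46. CDC25C, TTK and MAD2L1 of mitosis were lower by -1.44, -1.05 and -1.02.

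In the pair labelled p53, 41 genes were at least 2-fold higher and 73 lower in the truncated form, and in the pair labelled p73 117 and 25. Over every probe set the balance of the p53 pair turned, with 204 higher and 115 lower against 205 and 60 in the p73 pair. The actin 3' to 5' signal moved with truncation most in the p53 pair, from 2.16 to 1.22, against 1.74 to 1.61 in the p73 pair. That of GAPDH moved little, from 0.99 to 0.93 and from 0.92 to 0.96. The 2 controls thus differ, and by actin RNA quality is not separated from truncation in the p53 pair. The medians, p53 first, were 0.04 and 0.37 for arrest and repair, -0.15 and 0.46 for apoptosis, -0.26 and 0.66 for NF-kB and inflammation, 0.30 and -0.48 for mitosis and 0.30 and -0.36 for DNA replication. Across genes the 2 truncation differences had an r of -0.26 and a rho of -0.25. In the limma fit over both members 1 gene passed, S100A2, which fell by 1.23 ± 0.233 (SE) (adjusted p = 0.00957), with 128 genes at an unadjusted p under 0.05. That call ended with a floor at the 30th percentile, no floor, the mean of probe sets, every probe set on its own and eBayes without trend and robust. camera called genes linked to p63 and p73 (-0.26, from -1.02 in the p53 pair and 0.31 in the p73 pair), NF-kB and inflammation (0.37), immediate early genes (0.25), mitosis (-0.12) and stress genes (0.11), with adjusted p between 0.797 and 0.875 with an estimated correlation.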

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

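Chosen after the result was seen were the tests of an exchange of labels, of scaling in both cell lines, of a 24 h construct library taken at 0 h or from cells without the construct, and of other splits of the C2C12 libraries, as well as the fit that pools 0 h and 6 h. The limits that decide the TP73 and slope tests were revised after their values were seen. The difference of the 24 h changes, construct minus mock, set 8 C2C12 lists apart from the other genes in that interaction fit (camera, preset correlation). Their medians were -1.82 for the sarcomere, -0.67 for muscle membrane and metabolism, -0.55 for myogenic regulators, -0.61 for the interferon response, -0.60 for IGF signalling, -0.58 for extracellular matrix, 1.16 for DNA replication and 1.47 for mitosis. With an estimated correlation the adjusted p lay between 0.352 and 0.666.

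The missing rise of muscle genes in the construct library of 24 h was set against 4 technical explanations. Scaling is excluded, since the sarcomere median against mock was -2.7453 after quantile normalization, and so is a library taken at 0 h, since cholesterol synthesis was higher than at 0 h in 13 of 13 genes, with a median of 1.6355 and a lowest value of 0.38. Mock cells in place of those of the other construct libraries are excluded by the 131 genes that were at least 2-fold higher at 0 h and 6 h, whose median at 24 h was 1.2521, while Trp73 itself, below the floor in all 6 libraries, verifies no label. A library taken at 6 h stays open: the 6 h to 24 h changes of the 2 arms had an r across genes of 0.027746 (11991 genes), which that explanation predicts. The construct libraries of 6 h and 24 h differed by at least 2-fold in 46 genes higher and 18 lower, against 565 and 443 in mock. The residual spread of the additive fit alone would give 24.65 such genes in both directions together, which is no estimate of technical noise. A halt of differentiation by the construct may give the same values, so no table here separates it from a library taken at 6 h.

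The TP73 signal in the libraries labelled p53 and truncated p53, at least 242-fold and 183-fold over the floor, may come from an exchange of the p53 and p73 labels. That explanation needs p53 targets of arrest and repair to be higher under the p73 label in both forms, and the lower of the 2 medians was 1.0084. Genes linked to p63 and p73 were not part of that test and parted the labels in the full forms only. Their medians against GFP were 1.67 under the p53 and 0.42 under the p73 label in the full forms. In the truncated forms they were 0.73 and 0.78. Over both forms their median was -0.08 for the p73 relative to the p53 label, with 4 of 11 positive. A TP73 gene switched on by delivered p53 was predicted to lose signal with truncation like the other 12 genes at least 4-fold higher in that library, which changed by -1.06 at the median and by -1.49 to -0.55 in the middle 95%. TP73 changed by -0.39954, outside that range. It lay at 25983 on an array whose highest value was 30942, where differences may shrink, though this was not tested. The 12 genes were picked for being high in the full form, so that bound cannot decide and this explanation remains open. Against it stands a TP73 difference from GFP of 7.92 where no other gene exceeded 3.52. Nor does it account for TP73 at 2.57 and 10.6 in the libraries labelled p73 and truncated p73. Such values could arise if the probe set lay outside the delivered p73 sequence, which was not checked. Targets of p53 do not decide on this explanation. The MDM2 probe set used had 83.0 under the p53 label, below the floor, and 139 in GFP. Another MDM2 probe set had 129, near the floor of 107.4, and 66.9. Under the p73 label these 2 probe sets had 1999 and 2037. CDKN1A had 3174 under the p53 label and 718 in GFP. No other biological explanation was tested.

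In H1299 the truncated minus full medians had opposite signs in the 2 family members, 0.30 and -0.36 for DNA replication and 0.30 and -0.48 for mitosis, with the p53 label first, and these differences were not tested. For mitosis scaling is excluded, since the median over its genes of the p73 minus the p53 truncation difference was -0.761 after quantile normalization. That test did not cover DNA replication. A response of unequal strength in each library, which could follow from unequal infection, predicted slopes of truncated on full on opposite sides of 1: the slope was 1.0708 ± 0.0361 (SE across genes) for the p73 label, too near 1 to decide, and 0.444 for the p53 label. The genes were chosen for being at least 2-fold from GFP in the full form, which lowers such slopes. Both forms also share the GFP library, and the SE takes genes as independent, so these slopes do not decide. Unequal RNA quality also stays open and was not tested, and so does a difference between the constructs. The actin 3' to 5' signal was 2.16 and 1.22 in the p53 pair and 1.74 and 1.61 in the p73 pair. That of GAPDH differed little, with 0.99 and 0.93 in the p53 pair and 0.92 and 0.96 in the p73 pair.

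For the construct effect of C2C12, the real split of the libraries gave 73 genes, and 1 of the 10 splits, the real one, gave as many, with at most 10 genes in the others. In most splits, those with 10 genes among them, both libraries of a time fell in the same group. The tested term then rests on the libraries of 1 time, so those counts cannot be compared with 73. The other splits that, like the real one, parted the libraries of every time gave 0 genes. The 10 splits cannot give a share under 0.05.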

How the results depend on the processing

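The fits that pool 0 h and 6 h were added after the data were seen, and the other settings were fixed before. Causes of the moves given here were not tested. By design, an additive C2C12 fit without 1 of the 24 h libraries matches the remaining one exactly. Its residual spread then holds no departure from additive effects at 24 h. Of the counts, 114 stayed within 1.5 times and 102 did not. Among single genes of the fits 733 kept direction and threshold and 513 kept direction alone. Among list tests 587 kept both, 87 kept direction alone and 2 reversed. Of the gene differences of pairs 1878 moved by less than 1 on the log2 scale and 282 by more, and of the list medians of pairs 686 moved by no more than the spread (median absolute deviation) of their members, 16 by more and 5 reversed.

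The construct effect of C2C12 had 73 genes, and 110 with scaling to a common median, 114 with a floor at the 30th percentile, 17 at the 70th, 39 with the mean of probe sets, 135 with no time factor and 1495 without both 24 h libraries. Leaving out each library gave 20 to 1480 genes, with 35 without mock 0 h, 28 without construct 0 h, 22 without mock 6 h, 20 without construct 6 h, 1480 without mock 24 h and 1471 without construct 24 h. The 6 h time effect had 0 genes (limma, 685 at an unadjusted p under 0.05), and 1 with a floor at the 30th percentile, 2 with no floor and 931 without both 24 h libraries. Leaving out each library gave it 0 to 903, with 903 without mock 24 h and 886 without construct 24 h. The 24 h time effect had 0 genes (limma, 1394 at an unadjusted p under 0.05), and 2 with a floor at the 30th percentile and 6 with no floor. Leaving out each library gave it 0 to 3873, with 6 without mock 6 h, 421 without mock 24 h and 3873 without construct 24 h. With 0 h and 6 h pooled, the 809 genes of mock at 24 h became 15 with the mean of probe sets, 0 without trend and robust, and 0 to 0 on leaving out mock 0 h, construct 0 h, mock 6 h or construct 6 h. The difference of the 24 h changes had 0 genes (limma, 1983 at an unadjusted p under 0.05), and 2 after quantile normalization and 4 with no floor.

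In H1299 the 131 genes of p73 against p53 became 23 with a floor at the 30th percentile, 23 with no floor, 1 with the mean of probe sets, 52 with every probe set and 4 without trend and robust. The 1 gene of truncated against full became 0 (limma) with a floor at the 30th percentile, no floor, the mean of probe sets, every probe set and no trend and robust. The 4 constructs against GFP had 0 genes (limma, 279 at an unadjusted p under 0.05) in every setting run.

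Counts of genes at least 2-fold apart follow the floor, since a lower floor lets low signals differ by more. They are given as reported, then with a floor at the 30th percentile, at the 70th, with no floor and with every probe set. For construct against mock they were 425, 1494, 122, 4374 and 895 at 0 h, 380, 1303, 129, 4341 and 762 at 6 h, and 1584, 2799, 903, 5532 and 3202 at 24 h. In mock they were 200, 1024, 72, 4055 and 486 for 6 h against 0 h, and 1486, 2616, 931, 5415 and 2950 for 24 h against 0 h. In construct cells they were 275, 1266, 115, 4208 and 595 for 6 h, with 177 for the mean of probe sets, and 278, 1273, 120, 4142 and 618 for 24 h, with 167. Against GFP they were 324, 723, 128, 2701 and 680 for the p53 label, 144, 628, 66, 2635 and 236 for p73, and 338, 1017, 190, 2951 and 562 for truncated p73. For truncated p53 they were 58, 295, 22 and 2265. Truncated against full gave 114, 461, 31, 2448 and 319 for the p53 label and 142, 801, 42, 2617 and 265 for p73, with 93 for the mean of probe sets. Labelled p73 against p53 gave 381, 932, 142, 2838 and 785 for the full forms and 191, 773, 94, 2722 and 366 for the truncated forms.

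Reversed medians were IGF signalling at 0 h, 0.20 with a floor at the 30th percentile and 0.21 with no floor, blood cell markers at 6 h in construct cells, 0.14 with a floor at the 30th percentile, epithelial markers with the p53 label, 0.0074 with that floor, and ribosomal proteins with the p73 label, -0.0047 after quantile normalization. For DNA replication at 6 h camera's direction turned to up without construct 6 h while the median stayed negative at -0.0205, and leaving out each library gave medians from -0.642 (without mock 6 h) to -0.0205. For stress genes in construct cells, 24 h against the pooled early stage, leaving out each library gave medians from -0.0218 without construct 0 h to 0.639 without construct 6 h, against 0.256 with all libraries. Without both 24 h libraries the 24 h time effect could not be fitted, and leaving out libraries of the 4 H1299 constructs left no residual degree of freedom for p73 against p53 and truncated against full. Signal near background limits low genes, since the floor is the median of all values.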

Other observations

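The values of this part were picked after the results were seen and have no p-value. Cell cycle exit had a mock median of 0.46 at 24 h against 0 h (percentile 99.78 of matched random lists) and adipocyte markers 0.48 (percentile 98.13). Blood cell markers had 0.16, osteoblast markers -0.03 and smooth muscle and fibroblast markers 0.25. Immediate early genes had medians of -0.46 at 6 h and -0.75 at 24 h in the construct cells (percentile 0 at both times) and -0.28 and -0.09 in mock (percentiles 0 and 33.73). Their median was already 0.30 higher in the construct than in the mock library at 0 h (percentile 99.99), which enlarges the fall in the construct cells. Ribosomal proteins stayed between -0.07 and 0.10 in the 4 time pairs.

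In H1299 the metallothionein gene MT1H had an intensity of 1039 in GFP, 6648 and 3979 in the libraries labelled p53 and truncated p53, and 1987 and 5402 in those labelled p73 and truncated p73. The 3' GAPDH control probe set had 22661 in GFP, 24858 and 25158 in the libraries labelled p53 and truncated p53, and 30894 and 35205 in those labelled p73 and truncated p73. In C2C12 it lay between 31579 and 36639.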
